A study of Homo sapiens with 12 samples.

How the data were processed

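RNA of 12 samples was measured by sequencing of polyadenylated transcripts, in 4 labelled groups of 3 libraries: A431_control, A431_CM, HaCaT_control and HaCaT_CM, where CM stands for conditioned medium. Per the labels' protocols, cells grew in DMEM with 10% fetal calf serum to 80% confluence. HaCaT cells then received medium conditioned by A431 cells for 24 h. Which cells conditioned the medium for the A431 arm, and what medium the controls received, is not given in the sources used here. Libraries were made from 500 ng of RNA with a RIN above 7.5, using a SENSE mRNA-Seq V2 kit (Lexogen), per the labels' protocols.

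The authors deposited raw read counts per gene symbol for all 12 libraries in 1 table, with no normalization. Per the submitters' processing notes, the tools were STAR, HTSeq and DESeq2 1.0.19, and the genome build was hg19, with no role or settings given. The strand setting and the annotation are not given in the sources used here, so overlapping and antisense genes are uncertain. The table lists 23368 gene symbols and 5 bookkeeping lines. The bookkeeping lines held 38.9 to 44.1% of each library's total and stayed out of library sizes and tests. Of that total, 18.8 to 23.5% had no feature, 18.6 to 20.3% did not align uniquely and 1.01 to 1.24% were ambiguous. Reads that did not align uniquely were thus not assigned to genes. Members of near-identical families (SPRR2, SAA1 and SAA2, AKR1C, KRT6) therefore have uncertain counts, as do other keratin genes alike in sequence, KRT16 among them. The reference at hand is of another build, so no coordinates are given.

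The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12669 genes and removed 10699. Counts were scaled by TMM and fitted with the robust quasi-likelihood model, with 1 coefficient per group and 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, counts scaled to the library total, after TMM scaling, and errors of log2 fold changes are standard errors (SE). The 43 gene lists were written before the data were examined. Of these, 40 had 3 or more tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and 3 had none. Camera with an estimated correlation, fry, and DESeq2 1.42.0 served as alternatives. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

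The 4 planned comparisons were CM against control in each labelled line, the difference between those 2 responses, and A431_control against HaCaT_control. Another 4 were added after the data were examined: A431_CM against HaCaT_control, HaCaT_CM against A431_control, the difference between these 2, and A431_CM against HaCaT_CM. No library was regrouped. The rule for named genes took, per comparison, up to 10 called genes of each direction with the largest change, a mean of at least 5 CPM in the higher group and no overlap of the libraries, without clone names and pseudogenes. Chance gives no overlap for 10% of genes in 3 against 3. For a difference of responses it took 5 of each direction. It added up to 4 called members of each list described, with the smallest adjusted p, and always MYC, MTOR, RPS6KB1, RPS6, EIF4EBP1, AKT1 and EGFR. A fold against a group with 0 counts is a lower bound, computed from a floor of 3 counts summed over the group. With 1 to 3 counts the ratio has an exact 95% Poisson interval. The kit's reads are PCR products counted without molecular identifiers, so floors and intervals cover counting error only.

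The depth ranged from 7875239 to 15993204 gene counts per library. On simulated counts, with 200 genes changed by 1.5-, 2- or 4-fold, 92.4% of 4-fold, 37.3% of 2-fold and 1.49% of 1.5-fold changes were called for HaCaT_CM against HaCaT_control, among 12527 genes tested. For A431_CM against HaCaT_control, the shares were 86.4%, 28.4% and 0% over 12516 genes. For HaCaT_CM against A431_control, they were 89.4%, 38.8% and 0% over 12553 genes. The draws used 1 spread per gene for all groups and set no library apart from its group. The shares may thus not hold for this comparison, where replicate 1 of each group stood apart. All 12 pairs of libraries of 1 group differed by more than counting noise (chi-square per gene 3.49 to 152), so no library repeats another. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

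Replicate numbers were tested for pairing through the correlation of same-numbered libraries' deviations from their group means. For HaCaT_CM against HaCaT_control it was 0.50, 0.42 and 0.12, above 0.1 in each pair, which met the rule set for pairing. Differently numbered libraries were not compared, and the labels name no shared day or batch, so pairing is not shown. With the replicate block, 6925 genes were called in place of 7017.

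The alternatives tried were DESeq2 size factors, library size alone, no filter, a fit that is not robust, a replicate block, the DESeq2 Wald test, only the 6 libraries compared, and leaving out each library. Chosen after seeing the data were leaving out A431_control replicate 1 and HaCaT_CM replicate 1 together, and removing each library's trend over transcript GC content and length (splines with 4 degrees of freedom, 12236 of 12669 genes). The trend was first removed without centring, which also moved the scaling. A centred version was chosen after those results were seen, and both are reported.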

Results

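Transcript levels were measured by RNA sequencing in A431, an epidermoid carcinoma line known for its excess of the EGF receptor, and in HaCaT, an immortalized keratinocyte line. The title of the series asks how the secretome of skin cancer cells acts on the mTOR and MYC pathway in keratinocytes. Each line has a control group and a group given conditioned medium (CM), with 3 libraries per group and 12 in all. Gene counts for A431_control replicates 1 to 3 were 15993204, 9582239 and 8859553. They were 10308716, 9004875 and 12363870 for A431_CM, 9597133, 9126626 and 10050553 for HaCaT_control, and 7875239, 13558883 and 9099686 for HaCaT_CM.

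The cell line profile of the CM libraries went against their labels. EGFR, the receptor gene amplified in A431, was at 8907, 9605 and 9113 CPM in the A431_control libraries and at 701, 575 and 414 CPM in the HaCaT_control libraries. In the libraries labelled A431_CM it was at 651, 638 and 542 CPM, and in those labelled HaCaT_CM at 8675, 7108 and 6503 CPM. Over 235 genes that differed between the 2 control groups by at least 5 log2 units with at least 20 CPM in the higher one, each library was placed between HaCaT_control (0) and A431_control (1). The libraries labelled A431_CM lay at a median of 0.0294 to 0.0359 and those labelled HaCaT_CM at 1.00 to 1.03. Of these genes, 100% in the libraries labelled HaCaT_CM were nearer the A431 control, and 99.57% in those labelled A431_CM were nearer the HaCaT control. The groups are kept as labelled throughout, and every direction below is that of the labels.

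**Figure D1:**
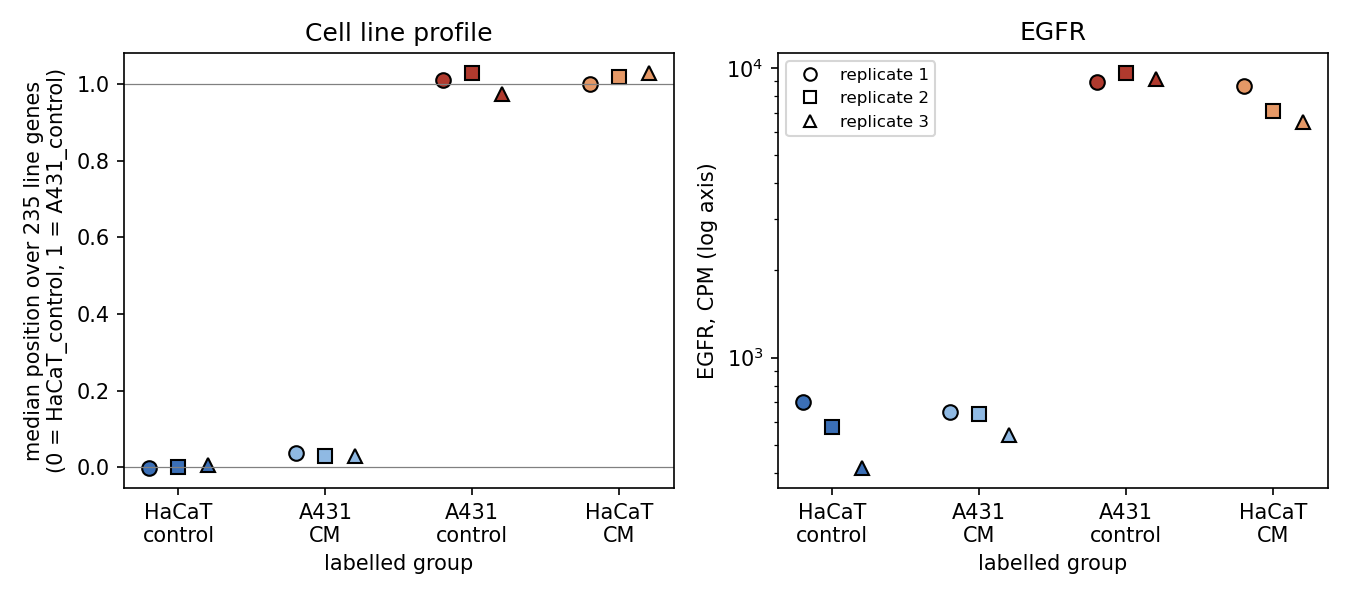
Median position of each library over 235 genes that separate the control groups (left; 0 is HaCaT_control and 1 is A431_control) and EGFR in CPM on a log axis (right), by labelled group, with 1 point per library. The libraries labelled A431_CM sit beside HaCaT_control, and those labelled HaCaT_CM beside A431_control.

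Replicate 1 of A431_control and of HaCaT_CM also stood apart from their groups. The mean correlation of log2 CPM across genes was 0.956 between A431_control replicate 1 and its own group, and 0.990 with replicates 2 and 3 of HaCaT_CM. For HaCaT_CM replicate 1 it was 0.970 with its own group and 0.984 with replicates 2 and 3 of A431_control. Genes are not independent replicates, so no p-value is attached. The first principal component held 83.8% of the variance and the second 7.75%.

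**Figure D2:**
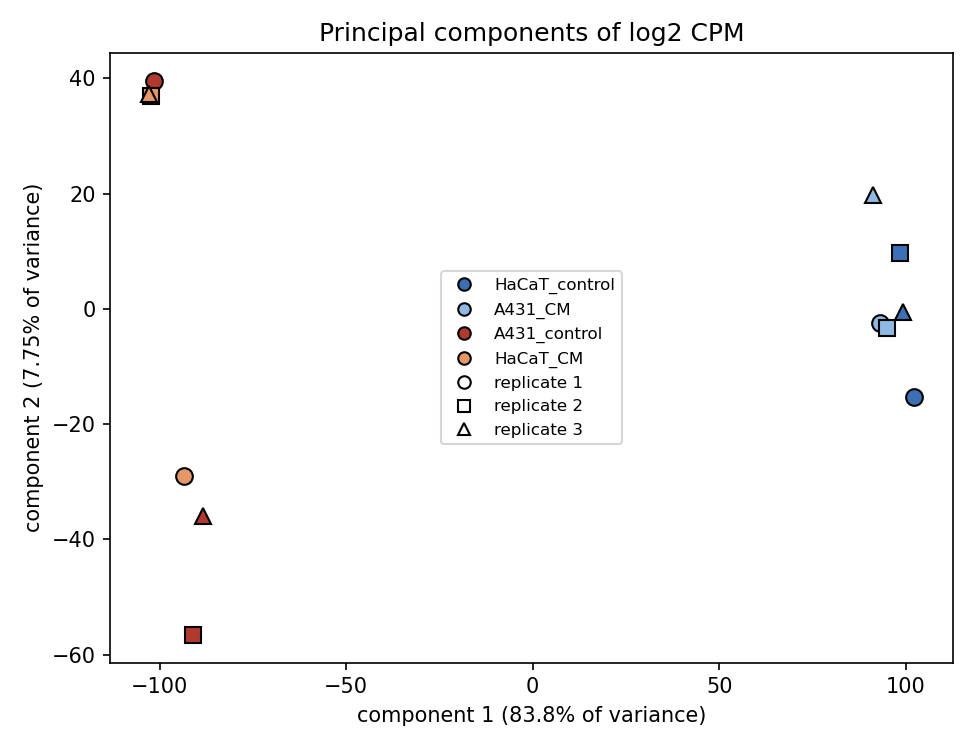
First and second principal components of log2 CPM, with 1 point per library, colour for the labelled group and shape for the replicate number. Component 1 (83.8% of variance) separates HaCaT_control and A431_CM from A431_control and HaCaT_CM. On component 2 (7.75%), A431_control replicate 1 lies beside HaCaT_CM replicates 2 and 3.

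The comparison of HaCaT_CM with HaCaT_control was planned for the response of keratinocytes to cancer cell medium, but its values set libraries with the A431 profile against libraries with the HaCaT profile. As labelled, EGFR was higher in the libraries labelled HaCaT_CM (7428 ± 1120 CPM, SD, n = 3) than in HaCaT_control (563 ± 144), a log2 fold change of 3.72 ± 0.198 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.19e-08). MYC, a growth-promoting transcription factor, rose from 62.1 ± 10.9 to 128 ± 16.6 CPM (log2 1.05 ± 0.18, edgeR adjusted p = 0.000344). RPS6KB1, which encodes the S6 kinase downstream of mTOR, rose by 1.33 log2 units, and RPS6, its ribosomal protein substrate, by 0.58. AKT1 fell by 0.89 log2 units, a call and direction lost when the uncentred GC and length trend was removed (log2 0.09, edgeR adjusted p = 0.565). MTOR (log2 0.03, edgeR adjusted p = 0.912) and EIF4EBP1 (log2 0.72, edgeR adjusted p = 0.12) did not pass the test. The keratin gene KRT14 of basal keratinocytes fell by 6.60 log2 units, from 6961 to 71.9 CPM, and the desmosomal cadherin gene DSG3 fell by 3.78.

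In all, 3309 genes were higher and 3708 lower in the libraries labelled HaCaT_CM, 7017 of 12669 tested. Several genes were at 0 counts in 1 of the groups. HBE1 was at least 110-fold, HLA-DPB1 at least 94.0-fold and ALDH5A1 at least 77.5-fold higher. NEFL was at least 2010-fold, DNAJC15 at least 1430-fold, COBL at least 873-fold and PHGR1 at least 768-fold lower. RGS16 had 3 counts in HaCaT_control, and its ratio was 313 (95% Poisson interval 107 to 1520).

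Of the 112 mTORC1-regulated genes tested, 56 were higher and 18 lower, over all genes tested and adjusted over the list alone, and ELOVL5 (log2 3.16), MTHFD2 (3.36) and SQLE (3.00) were among those higher (camera adjusted p = 0.000418, and adjusted p = 0.243 with an estimated correlation). Of 61 MYC target genes, 35 were higher and 2 lower by both counts, among them TMEM97 (1.57) and NOP56 (1.56), with a camera adjusted p = 2.31e-05, and adjusted p = 0.361 with an estimated correlation. Cholesterol synthesis genes were higher in 16 of 25 and lower in none, adjusted over the list alone as well, with HMGCS1 at log2 4.09 and MSMO1 at 2.93 (camera adjusted p = 0.00019, and adjusted p = 0.052 with an estimated correlation). Of 17 basal keratinocyte genes, 12 were lower and 3 higher by both counts (camera adjusted p = 0.00525, and adjusted p = 0.162 with an estimated correlation). Epithelial junction genes were lower in 20 of 32 and higher in 3, adjusted over the list alone as well (camera adjusted p = 0.00174, and adjusted p = 0.162 with an estimated correlation). Camera called 19 of 40 lists, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05, while fry called 34.

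The comparison of A431_control with HaCaT_control gives the baseline of the lines. EGFR was 4.03 ± 0.201 log2 units higher in A431_control (edgeR adjusted p = 1.46e-08), and MYC was 1.39 ± 0.181 higher (edgeR adjusted p = 4.01e-05). PTPRZ1 was at least 552-fold, LDOC1 at least 529-fold and CDKN2B, a cell cycle inhibitor gene, at least 412-fold lower in A431_control. HLA-DPB1 was at least 144-fold, HBE1 at least 119-fold and KRT31 at least 97.7-fold higher. In all, 3125 genes were higher and 3290 lower, 6415 together. The share higher was 48.7%, against 43.8% with library size alone and 57.6% with the uncentred GC and length trend removed. Cholesterol synthesis genes were higher in 17 of 25 (18 adjusted over the list alone; camera adjusted p = 8.29e-06, and adjusted p = 0.019 with an estimated correlation). Interferon-stimulated genes were higher in 30 of 49 and lower in 7 (33 and 7 adjusted over the list alone; camera adjusted p = 8.29e-06, and adjusted p = 0.0198 with an estimated correlation). Camera called 18 of 40 lists, and 2 with an estimated correlation.

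In the planned comparison of A431_CM with A431_control, EGFR fell by 3.92 log2 units in the libraries labelled A431_CM (edgeR adjusted p = 1.88e-08), and RPS6 fell by 0.71 (edgeR adjusted p = 0.00489). MYC was higher, at 282 ± 32.0 CPM against 162 ± 27.8 in A431_control (SD, n = 3), a log2 fold change of 0.80 ± 0.178 (edgeR adjusted p = 0.00256). MYC was also higher in HaCaT_CM than in HaCaT_control. Both comparisons set 1 line profile against the other, so they do not show a shared response to CM. LDOC1 was at least 565-fold, PTPRZ1 at least 529-fold, PTPRB at least 498-fold and BMP4, a secreted growth factor gene, at least 373-fold higher. EGFLAM was at least 234-fold, TFPI at least 228-fold and PRAME, a tumour antigen gene, at least 157-fold lower. In all, 3243 genes were higher and 2883 lower, 6126 together. With library size alone, the median of all genes shifted by 0.11 log2 units, and 60.7% of calls were higher in place of 52.9%. Cholesterol synthesis genes were lower in 17 of 25 (18 adjusted over the list alone; camera adjusted p = 1.18e-05, and adjusted p = 0.018 with an estimated correlation). Of 112 mTORC1-regulated genes, 44 were lower and 15 higher (46 and 15 adjusted over the list alone; camera adjusted p = 0.00168, and adjusted p = 0.288 with an estimated correlation). Camera called 17 of 40 lists, and 1 with an estimated correlation.

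Across genes, the 2 labelled CM responses, which share no library, ran against each other (Pearson r = -0.935, Spearman rho = -0.811 over 12669 genes), with opposite signs for 80% of genes and the same sign for 20%. Of the genes higher in HaCaT_CM, 2127 were lower in A431_CM, where independent lists would share 753, and 2593 were lower in HaCaT_CM and higher in A431_CM (949 if independent). Only 56 were higher in both (847 if independent) and 18 lower in both (844 if independent). The labelled HaCaT response correlated with the difference of the control groups at r = 0.973 and covariance 5.32. Unchanged groups simulated against the same 3 controls gave r = 0.503 (SD 0.00722, 20 draws) and covariance 0.046, a difference in covariance of 5.27. Called genes shared were 2641 higher in both (816 if independent) and 2945 lower in both (963 if independent). Both comparisons subtract the same controls and are thus not independent, so these overlaps are descriptive only. The 3 controls cannot be split with 2 libraries in each part, so a small part of the excess may come from the shared controls. The simulated covariance, 0.0439 to 0.0476 over 20 draws against 5.32 observed, argues against them as its main source.

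The libraries labelled A431_CM were set against HaCaT_control, the control group with the same line profile, as a comparison added after the data were examined. MYC was 282 ± 32.0 CPM against 62.1 ± 10.9 (SD, n = 3), a log2 fold change of 2.18 ± 0.185 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.33e-05). Genes of inflammation rose with it: IL8, a neutrophil-attracting chemokine, from 1.91 to 24.4 CPM (log2 3.67 ± 0.456), CCL2, a monocyte-attracting chemokine (3.33 ± 0.282), and the acute phase gene SAA1 (3.51 ± 0.244). The antimicrobial S100A9 rose by 2.93 log2 units and the apoptosis inhibitor BIRC3 by 2.88. SPRR2D (4.36) and SPRR2A (3.11), cornified envelope genes, rose as well, with uncertain counts in that family. KRT1, a keratin of differentiating keratinocytes, fell by 2.54 log2 units, from 464 ± 106 to 79.4 ± 28.7 CPM, and the desmosomal gene DSG1 fell by 2.58. LMO1 fell by 3.48, ALDH1A1 by 2.78 and IGFBP2 by 2.44. Of 105 genes named in this comparison, 55 kept the same test outcome in every setting and 50 did not. EGFR (log2 0.12), MTOR (0.19), RPS6KB1 (0.58), RPS6 (-0.17), EIF4EBP1 (0.30) and AKT1 (0.06) did not pass the test, with edgeR adjusted p-values of 0.813, 0.724, 0.215, 0.691, 0.75 and 0.948.

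**Figure D3:**
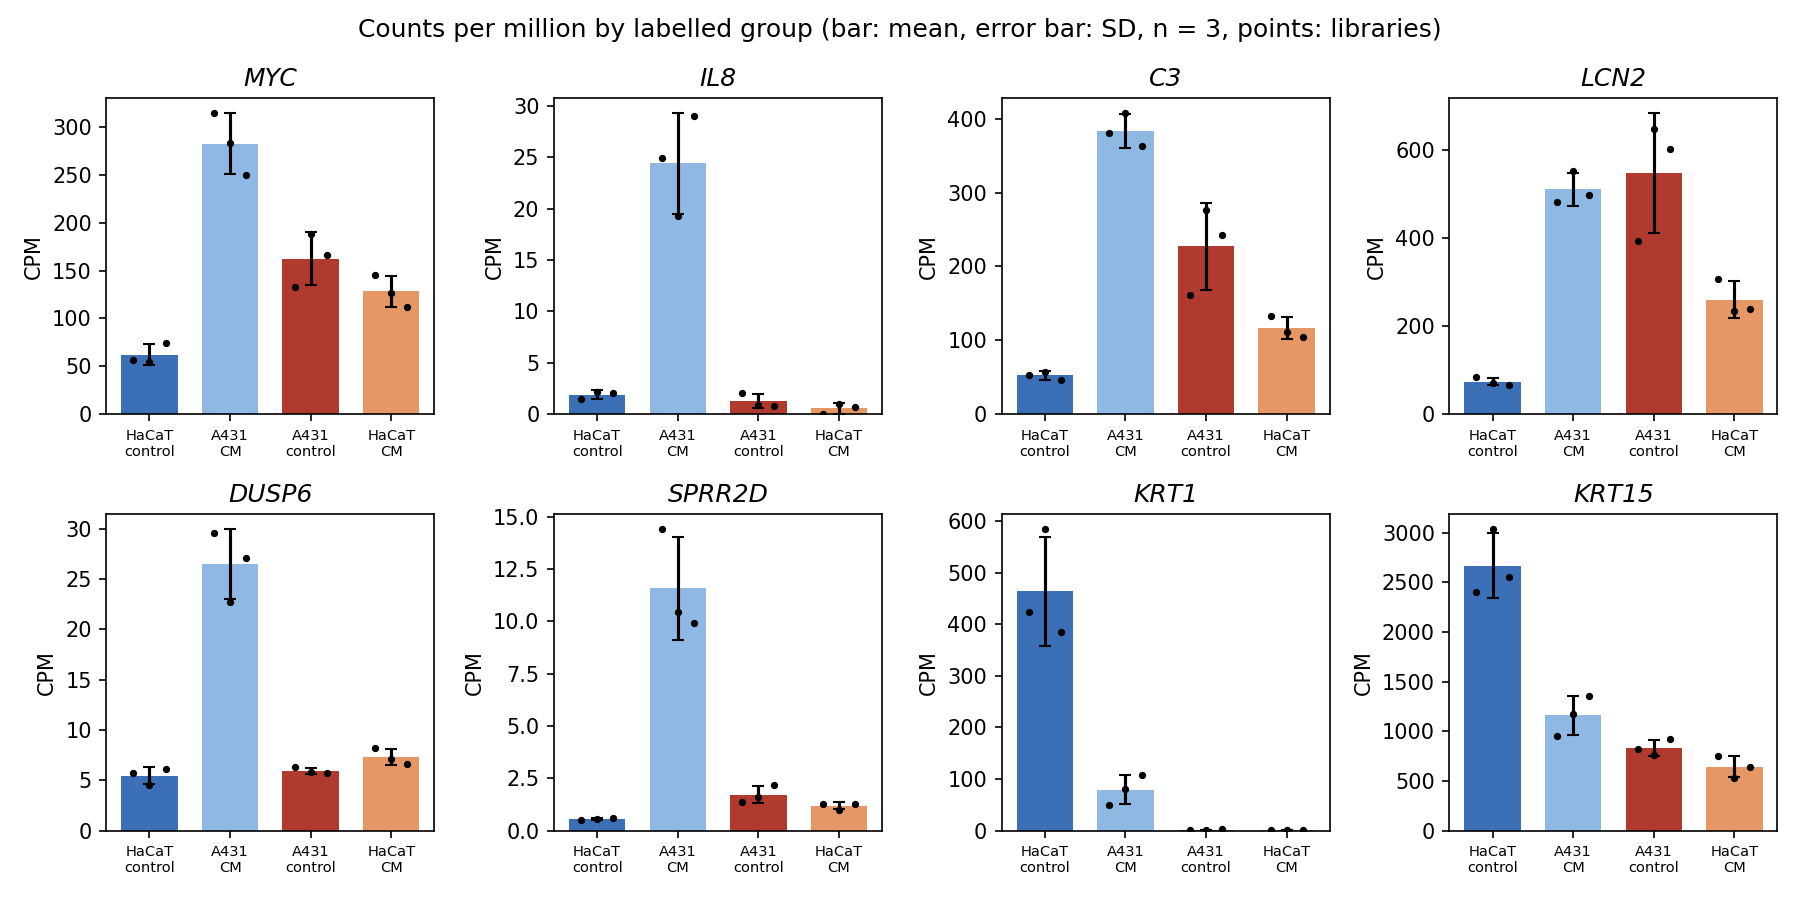
CPM of 8 genes by labelled group; bars are means, error bars are SD (n = 3), and points are libraries. MYC is at 282 CPM in the libraries labelled A431_CM and at 62.1 CPM in HaCaT_control, while KRT1 is at 79.4 and 464 CPM.

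Of 32 inflammatory cytokines and NF-kB targets, 22 rose and none fell (24 and 0 adjusted over the list alone), among them C3, the central complement component (log2 2.87), and CXCL1 (1.87); camera gave an adjusted p = 3.16e-28, and adjusted p = 4.61e-05 with an estimated correlation. ERK feedback and immediate-early genes rose in 15 of 31 (20 adjusted over the list alone), with the ERK phosphatase genes DUSP5 at log2 2.46 and DUSP6 at 2.28 (camera adjusted p = 1.16e-12, and adjusted p = 0.158 with an estimated correlation). MYC target genes rose in 13 of 61 (24 adjusted over the list alone), with the nucleolar genes NOLC1 at 1.33, NOP56 at 1.14 and WDR43 at 1.35 (camera adjusted p = 2.95e-11, and adjusted p = 0.158 with an estimated correlation). Ribosome assembly factors rose in 13 of 68 (21 adjusted over the list alone), with POLR1B, a subunit gene of RNA polymerase I, at 1.11 and RRS1 at 1.59 (camera adjusted p = 2.3e-10, and adjusted p = 0.158 with an estimated correlation). Of 112 mTORC1-regulated genes, 5 rose, among them HK2 (0.91), and 3 fell, among them NUPR1 (-1.35), or 14 and 4 adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.601).

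Activated keratinocyte genes rose in 6 of 17 and fell in 1 (8 and 4 adjusted over the list alone), with the secreted defence genes LCN2 at log2 2.78 and PI3 at 2.29, while KRT16, a keratin of activated keratinocytes, fell by 1.95 (camera adjusted p = 0.00551, and adjusted p = 0.158 with an estimated correlation). Basal keratinocyte genes did not pass as a list (camera adjusted p = 0.244), with KRT15 at -1.20, KRT14 at -0.88 and the laminin gene LAMA3 at 0.94, called, so 1 of 17 rose and 2 fell (3 and 5 adjusted over the list alone). Cytosolic ribosomal protein genes were shifted down as a list of 75 with 1 member called, RPSA at -0.53, and 0 adjusted over the list alone (camera adjusted p = 2.77e-09, and adjusted p = 0.202 with an estimated correlation). Oxidative phosphorylation genes were likewise shifted down as a list of 77, with NDUFS3 (-0.54) called and 0 adjusted over the list alone (camera adjusted p = 2.25e-09, and adjusted p = 0.183 with an estimated correlation). Camera called 16 of 40 lists, 1 of them with an estimated correlation.

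In all, 453 genes were higher and 197 lower in the libraries labelled A431_CM than in HaCaT_control, 650 together. The count was 369 with a replicate block, 1202 by the DESeq2 Wald test, 2488 with only the 6 libraries compared and 3137 without replicate 1 of A431_control and of HaCaT_CM, and 2536 with the GC and length trend removed. It was 208, 299 and 349 without A431_CM replicates 1, 2 and 3, and 313, 221 and 399 without HaCaT_control replicates 1, 2 and 3. Removing the uncentred trend gave 2678 calls, 48.3% of them higher in place of 69.7%.

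The libraries labelled HaCaT_CM were set against A431_control in the same way. Of 41 genes named in this comparison, 0 kept the same test outcome in every setting. CYP1A1 (log2 1.83 ± 0.23) and CYP1B1 (1.21 ± 0.173), targets of the aryl hydrocarbon receptor, and the replication genes MCM10 (1.51 ± 0.195) and CLSPN (1.21 ± 0.205) were higher in the libraries labelled HaCaT_CM. The list of 5 aryl hydrocarbon receptor targets did not pass (camera adjusted p = 0.166), with 2 higher and 0 lower, or 2 and 1 adjusted over the list alone. TXNIP, a glucose-responsive gene, fell by 1.68 ± 0.167 log2 units, from 649 ± 20.9 to 203 ± 21.0 CPM (SD, n = 3; edgeR adjusted p = 0.00368). The circadian genes PER1 and NR1D1 fell by 2.13 and 2.11. MYC was at log2 -0.34 (edgeR adjusted p = 0.366), EGFR at -0.31 (edgeR adjusted p = 0.412) and MTOR at 0.30 (edgeR adjusted p = 0.535), none of them called. Genes of G1/S and DNA replication rose in 4 of 47 (19 adjusted over the list alone; camera adjusted p = 2.13e-16, and adjusted p = 0.0686 with an estimated correlation). Inflammatory cytokines and NF-kB targets fell in 2 of 32, CXCL1 (-0.92) and C3 (-0.96), or 11 adjusted over the list alone (camera adjusted p = 1.7e-06, and adjusted p = 0.00694 with an estimated correlation). Interferon-stimulated genes fell in 1 of 49, OASL at -1.04, or 8 adjusted over the list alone (camera adjusted p = 5.53e-06, and adjusted p = 0.00694 with an estimated correlation). The mTORC1-regulated genes did not pass (camera adjusted p = 0.0765), with 2 of 112 called by both counts, RDH11 and MCM4, both higher. Camera called 15 of 40 lists, of which 2 stayed with an estimated correlation, 9 without replicate 1 of both groups, 10 without A431_control replicate 1 and 11 with the GC and length trend removed.

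In all, 26 genes were higher and 39 lower in that comparison, and the count rested on single libraries. It was 3334 without A431_control replicate 1, 86 without HaCaT_CM replicate 1, 2 and 1 without A431_control replicates 2 and 3, and 1 and 3 without HaCaT_CM replicates 2 and 3. Without replicate 1 of both groups it was 7305. It was 33 with no filter, 1 with a replicate block, 548 by the DESeq2 Wald test and 1258 with the GC and length trend removed. With only the 6 libraries compared, edgeR called 0 genes, with 854 at an unadjusted p under 0.05. With library size alone, 60.3% of calls were higher in place of 40.0%.

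**Figure D4:**
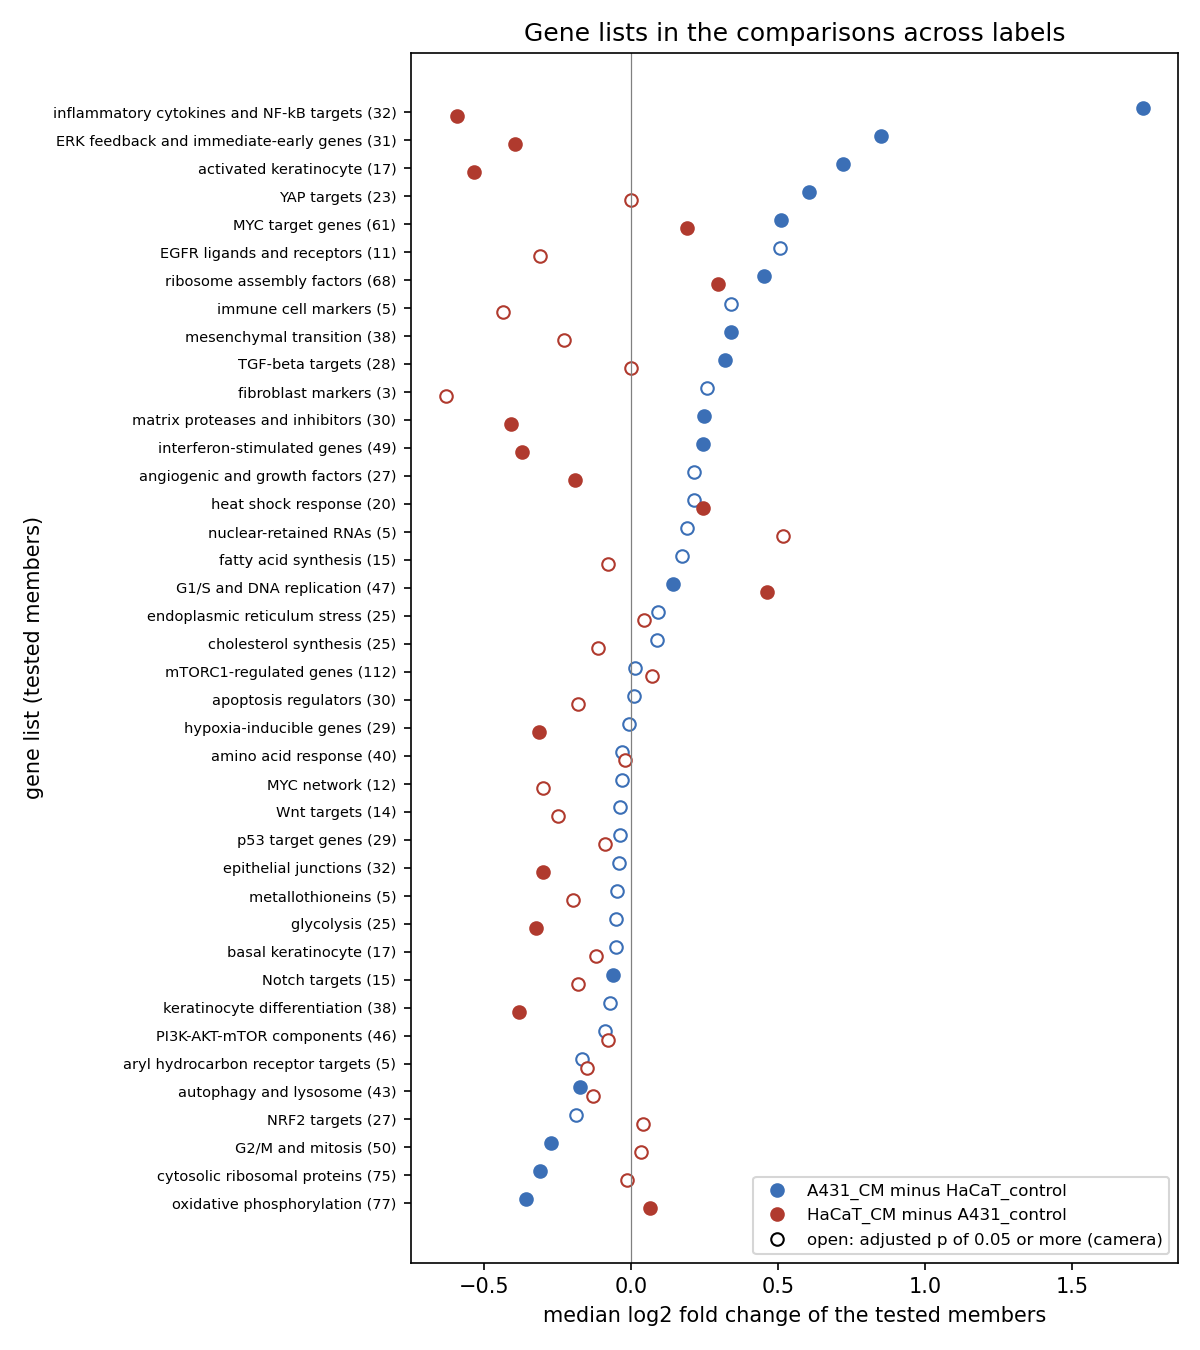
Median log2 fold change of the tested members of 40 gene lists in A431_CM minus HaCaT_control (blue) and HaCaT_CM minus A431_control (red), as labelled; filled points passed camera at adjusted p under 0.05. Inflammatory cytokines and NF-kB targets are shifted up in the first and down in the second.

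The remaining pair of labelled groups, A431_CM against HaCaT_CM, held 3507 higher and 2924 lower genes, 6431 together. Camera called 23 of 40 lists there, 1 of them with an estimated correlation, and cholesterol synthesis genes were lower in 16 of 25, adjusted over the list alone as well (camera adjusted p = 0.000268, and adjusted p = 0.0458 with an estimated correlation). Between A431_CM against HaCaT_control and HaCaT_CM against A431_control, which share no library, the log2 fold changes correlated at r = 0.172 (rho = 0.259), and single sets of same-numbered libraries gave -0.0134, -0.13 and 0.311. Called genes shared were 11 higher in both (0.93 if independent), 8 lower in both (0.606 if independent), 8 higher in the first and lower in the second (1.39 if independent) and none lower in the first and higher in the second (0.404 if independent).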

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

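Of the tests in this part, those of the exchanged names, of a line taking on the other profile, of mixed cells, of the exchange of replicate 1 and both tests of depth were chosen after the result was seen, as was every comparison across labels.

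A test of the difference between the 2 labelled CM responses set these results apart. The responses as labelled differed for 7976 genes and, by camera, 19 gene lists, 1 of them with an estimated correlation. Each CM group carried the profile of the other line. These values thus hold the difference between the lines and cannot be read as different responses to CM. EGFR differed by 7.64 log2 units, RPS6KB1 by 1.5, RPS6 by 1.29, EIF4EBP1 by 1.46 and AKT1 by -1.55 (edgeR). For genes at or near 0 counts in some groups no size is given, and the edgeR adjusted p was 3.59e-08 for HLA-DPB1, 2.94e-06 for KRT31, 7.02e-08 for UGT1A10, 1.89e-08 for EMR1, 3.86e-08 for HBE1, 6.99e-09 for PTPRZ1, 1.3e-10 for DNAJC15, 5.84e-10 for NEFL, 8.35e-09 for PRSS3 and 3.98e-09 for PTPRB. Of 100 splits of these libraries, 1, the real one, gave as many genes (7976, highest other 3994). For lists it was also 1 (19, highest other 18), at the preset correlation. Both shares were under 0.05. Most other splits mix the 2 line profiles within a group, which favours the real groups in advance. No conclusion on chance is drawn from these counts.

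A test of the difference between A431_CM against HaCaT_control and HaCaT_CM against A431_control called 111 genes and, by camera, 17 gene lists, 4 of them with an estimated correlation. SAA2 differed by 5.50 log2 units, SPRR2D by 4.87, IL8 by 4.72, SAA1 by 4.30 and MYC by 2.53, while EDN2 differed by -2.62, MIR22HG by -2.38, ID2 by -1.69, RPTN by -1.66 and ZNF323 by -1.37 (edgeR). PDZK1IP1, with 1 count in HaCaT_control, had an edgeR adjusted p = 0.000995. As many genes came from 9 of 100 splits (111, highest other 5408), so chance was not excluded for the gene count, and splits with several times the real count point to a structure of the samples. As many lists came from 3 of 100 splits (17, highest other 20, at the preset correlation), a share under 0.05. A split gave more lists than the real groups, and the gene counts point to a structure of the samples. The share thus does not exclude chance for the lists either.

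The first pattern is the line profile of the CM libraries. Against a line taking on the other profile within 24 h, the 99 genes found in HaCaT_control and at 0 counts in A431_control kept 0.116% of their summed level in the libraries labelled HaCaT_CM. Against mixed cells, the 10 genes found only in A431_control kept 0.839% of theirs in the libraries labelled A431_CM. At least 99.57% of line genes in both CM groups lay nearer the other line's control, so exchanged line names, or CM titles that name the source of the medium, are candidate explanations. The values do not separate these 2, and no biological explanation beyond the change of profile was tested.

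The second pattern is that replicate 1 of A431_control and of HaCaT_CM lay nearer each other's group. An exchange of these 2 libraries may explain it. The split that exchanges them called 7536 genes, the most of the 10 splits. The 2 were singled out from the same values, so that count restates the pattern and adds no support for an exchange. GC content or transcript length bias may explain the place of HaCaT_CM replicate 1. Its difference in mean correlation turned to -0.0025 with the trend removed and met the test set for it. The bias does not explain all of A431_control replicate 1, which stayed nearer the other group (0.990 against 0.983, a difference of 0.0065 above the range of 0.0055). The trend was weak in HaCaT_CM replicate 1 itself, where it explained 1.64% of the variance around the mean of all libraries. It explained 20.7% in A431_control replicate 1, and 18.3% and 17.2% in HaCaT_CM replicates 2 and 3. The next highest was 8.06%, in A431_control replicate 2. Depth met the test first set for it, as 2 of the 2 libraries lie outside the range of the other 10, from 8859553 to 13558883 gene counts. A431_control replicate 1 lay above that range (15993204) and HaCaT_CM replicate 1 below it (7875239). That test does not relate depth to the group a library lies near, so it gives little support to depth. A further test, added after that outcome was known, argues against depth as the whole cause, since with all libraries thinned to the shallowest the smaller difference stayed at 0.014; exchange, trend and an untested effect of CM stay open.

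The third pattern is the set of rises and falls in A431_CM against HaCaT_control. Against RNA of A431 cells, the share seen in the genes found only in A431_control would give a median of 0.418% of the rise over 453 genes, with at least 10% of it in 15 genes and at least 50% in 1. Genes lower in A431_control than in HaCaT_control enter with a share below 0, which lowers that median. The 197 genes that fell were not covered by this test. For GC content or length bias, 98% of the 650 calls kept their direction and call with the trend removed, which met the rule set against it. That fit called 2536 genes, so a call was easily kept, and the share alone does not decide on the bias. In the 6 libraries compared, the trend explained 0.195 to 7.08% of the variance around the mean of all libraries. A response to CM in cells with the HaCaT profile was not tested, and the meaning of the label is open.

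Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Where the groups compared carry different line profiles, every other split mixes both profiles in each group, which favours the real groups in advance. This holds for all pairs below except A431_CM against HaCaT_control and HaCaT_CM against A431_control. No conclusion on chance is drawn from these counts. As many genes came from 1 of 10 splits for HaCaT_CM against HaCaT_control (7017, highest other 0), A431_CM against A431_control (6126 and 0), A431_control against HaCaT_control (6415 and 0), A431_CM against HaCaT_control (650 and 0) and A431_CM against HaCaT_CM (6431 and 0). As many came from 2 of 10 for HaCaT_CM against A431_control (65 and 7536), where the larger count points to a structure of the samples. For lists, the real and highest other counts in the same order were 19 and 18, 17 and 13, 18 and 13, 16 and 15, and 23 and 16, each from 1 of 10 splits. For HaCaT_CM against A431_control they were 15 and 16, from 2 of 10.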

How the results depend on the processing

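All alternatives for the comparisons across labels, the setting without replicate 1 of A431_control and HaCaT_CM, both removals of the GC and length trend, and library size alone for lists were chosen after the data were seen. The uncentred trend was run first, and the centred one was chosen after its results.

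Counts of genes for the 4 planned comparisons and for A431_CM against HaCaT_CM stayed within 1.5 times under every alternative run. For A431_CM against HaCaT_control (650), the count was 369 with the replicate block, 1202 by DESeq2, 2488 with the 6 libraries alone, 3137 without both replicates 1, 2536 with the trend removed, 2678 uncentred and 208 to 399 leaving out 1 library. For HaCaT_CM against A431_control (65), it was 33 with no filter, 1 with the block, 548 by DESeq2, 0 with the 6 libraries alone (854 at an unadjusted p under 0.05), 7305 without both, 1258 and 1286 with the trend removed, centred and not, and 1 to 3334 leaving out 1 library. For the difference between these 2 (111), it was 54 with the block, 369 by DESeq2, 5570 without both, 906 and 899 with the trend removed, and 58 to 769 leaving out 1 library. Replicate 1 of A431_control and of HaCaT_CM is in neither group of A431_CM against HaCaT_control. Without both, the median of all genes there shifted by -0.0091 log2 units, and 100% of the 650 calls were kept. The spread was estimated over all 12 libraries, so the count of 650 depends on these 2 as well. Genes that did not pass there may have been missed for that reason. The cause of the other changes in count was not tested.

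The uncentred trend moved the median of all genes by up to 0.38 log2 units and the share of calls that were higher to 57.7% from 47.2% for HaCaT_CM against HaCaT_control, 57.6% from 48.7% for A431_control against HaCaT_control, 40.3% from 52.9% for A431_CM against A431_control, 39.8% from 54.5% for A431_CM against HaCaT_CM, 59.2% from 48.6% for the difference of the labelled responses, and 61.8% from 91.9% for the difference across labels (79.5% centred, 54.9% without both replicates 1). For A431_CM against HaCaT_control, 69.7% became 53.7% without both replicates 1 and 54.7% with the 6 libraries alone. AKT1 in HaCaT_CM against HaCaT_control turned to log2 0.087 (edgeR adjusted p = 0.565); its adjusted p was 0.0118 as reported. No other named gene and no list turned with a call. With an estimated correlation, lists called fell to 0, 1, 2 and 1 for HaCaT_CM, A431_CM, the controls and the difference of responses, and to 1, 2, 1 and 4 for A431_CM against HaCaT_control, HaCaT_CM against A431_control, A431_CM against HaCaT_CM and the difference across labels. Fry called 34, 32, 31 and 32 in the first 4.

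The correlation of the labelled responses (-0.935) was -0.886 without both replicates 1 and -0.941 to -0.907 leaving out 1 library. That with the line difference (0.973) was 0.928 and 0.949 to 0.976. Same-numbered libraries did not all deviate together outside HaCaT_CM against HaCaT_control (r = 0.26, -0.15 and 0.049 for A431_CM against HaCaT_control; -0.83, -0.66 and -0.41 for HaCaT_CM against A431_control). Of named genes, 168 of 175, 164 of 169, 165 of 170 and 162 of 168 kept call and direction in every setting for the planned comparisons in the order above, against 55 of 105 and 0 of 41 for the first 2 across labels.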

Other observations

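The comparisons described in this part were chosen after the data were examined; the gene lists were not. In A431_CM against HaCaT_control, YAP target genes rose in 10 of 23 (14 higher and 1 lower adjusted over the list alone), with the coagulation initiator F3 at log2 2.07 and IGFBP3 at 1.54 (camera adjusted p = 7.22e-09, and adjusted p = 0.132 with an estimated correlation). ANKRD1, with 2 counts in HaCaT_control, had a ratio of 25.8 (95% Poisson interval 7.13 to 213). Genes of mesenchymal transition rose in 10 of 38 and fell in 1 (13 and 3 adjusted over the list alone), with PLAUR, the urokinase receptor, at 1.64 and THBS1 at 1.10 (camera adjusted p = 8.41e-05, and adjusted p = 0.158 with an estimated correlation). Of 30 matrix proteases and inhibitors, 6 rose and 1 fell (7 and 3 adjusted over the list alone), with ADAM19 at 2.27 and PLAT at 1.65 (camera adjusted p = 0.0396, and adjusted p = 0.183 with an estimated correlation). Notch targets fell in 3 of 15, adjusted over the list alone as well, HEY1 (-0.90), NOTCH3 (-1.13) and HES5 (-1.06), with a camera adjusted p = 0.0396, and adjusted p = 0.372 with an estimated correlation.

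NRF2 target genes did not pass as a list there (camera adjusted p = 0.0505), while 4 of 27 fell (5 lower and 1 higher adjusted over the list alone). These were the aldo-keto reductase genes AKR1C1 (-2.25), AKR1C2 (-1.57), AKR1C3 (-1.56) and AKR1B10 (-1.06), whose counts are uncertain within the family. TGFA (1.04) and NRG1 (1.26), ligands of the EGF receptor family, rose, and their list of 11 did not pass (camera adjusted p = 0.171). CYP1A1 rose by 1.08 in that comparison and by 1.83 in HaCaT_CM against A431_control, CYP1B1 by 0.75 and 1.21, and NRG1 by 1.26 and 1.18. In HaCaT_CM against A431_control, these 3 lost their call with a replicate block and with only the 6 libraries compared, as 0 of 41 named genes there kept it in every setting, and in A431_CM against HaCaT_control CYP1A1 and CYP1B1 lost theirs with the block. The list of aryl hydrocarbon receptor targets did not pass in either comparison (camera adjusted p = 0.84 and 0.166, in the order of A431_CM and HaCaT_CM).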
